A study of Mus musculus with 13 samples.

How the data were processed

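RNA sequencing data of 13 mouse tumours were analysed, 6 labelled sgControl RPP and 7 labelled sgKdm6a RPP. Per the labels' protocols, tumours were taken at necropsy and flash-frozen, RNA was extracted with a column kit including DNase digestion, and libraries were made with a kit that does not keep the strand and sequenced as read pairs. The submitters' processing notes name STAR, DESeq2 and the mm10 build, without versions. The program that counted reads and the annotation release are not given in the sources used here. Groups were taken from the genotype label, and replicates were numbered in accession order, so the numbers pair no tumours.

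The authors deposited raw gene counts in a pair of tables, of which one adds gene names, and FPKM in another pair; within each pair 0 values differed. Counts were whole numbers for 54532 genes. The deposited FPKM equal the count divided by the gene length and by 1 constant per tumour, within 1e-06 in all 13 tumours. That constant is 0.883 to 1.12 times the total count, so the authors rescaled library sizes by a method not given in the sources used here. A table of the authors' group means of FPKM equals the means of the tumour values and was only checked. There were 15 gene names that a spreadsheet had turned into dates, and these were restored from a reference table by gene identifier. Of the identifiers, 54495 were found in the GENCODE M21 annotation of mm10 and 53585 had the same start, end and strand there, so coordinates are given as deposited. Where 1 symbol belongs to several identifiers, the one with the most reads was used. Because strand was not kept, reads from a stretch shared by genes on opposite strands cannot be told apart.

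The total count per tumour was 16835726 to 22910187, and no 2 tumours were identical. The detection limit was set at 3 counts per tumour.

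Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM, dispersions were estimated with the robust option, and genotype was tested by the quasi-likelihood F test with robust shrinkage and no covariate. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM used the TMM-scaled library sizes, and log2 CPM a prior count of 2. Gene lists with at least 5 tested members were compared with all other genes by camera from limma 3.58.1, with a preset correlation of 0.01, again with an estimated correlation, and by fry, which tests whether the genes of a list move, on balance, one way. Single values were compared by two-sided exact permutation over all 1716 splits of the tumours into 6 and 7, for which the smallest p is 5.83e-04. The similarity of tumours with a shared number used all 105 pairings and was one-sided.

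The genes named were set before the data were examined: the 4 guide targets; 7 subtype and MYC family genes; up to 10 genes of largest change per direction past the threshold, or, where fewer than 5 pass, the genes of smallest p to a total of 5, with a mean of at least 1 CPM in a group and a symbol that is not a Gm-number, Rik or LOC name; up to 4 members of smallest p of each list described; and Xist with the Y-linked list. Within the part on lists, 2 members of smallest p are printed for each list called by camera and for each subtype list, and the others are given as counts. That narrowing was made after the data were seen. Some genes and a list that the rule takes were tested, and their results are not reported here. Cerkl and Col7a1 were named after their values were seen. Ddx3x, Eif2s3x and Kdm5c, and 3 neighbours of Neurod1, were named for tests written before their values were seen.

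Scripts were tested on simulated data with the means, dispersions and library sizes of this comparison for 16575 genes, of which 200 were changed. For sgKdm6a against sgControl, edgeR recovered 14.8% of genes changed by 1 on the log2 scale, 57.5% of those changed by 2 and 90% of those changed by 4, and 1 of 114 calls was an unchanged gene. With nothing changed, 0 genes and 0 lists were called. The genes were simulated independently of each other, so this does not test camera on lists whose genes are correlated. Outlying tumours and tumours of one animal were not simulated either, so the shares recovered may exceed what the real tumours allow.

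Alternatives set before the data were examined were DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts, a filter of 1 CPM in 6 tumours, a fold minimum of 1 on the log2 scale, limma-voom with quality weights, counts summed over shared title numbers or also over a shared prefix, limma-voom with a correlation between tumours of a shared number, the number series of the titles as a term or as separate fits, a term for the mean of the Y-linked list, a term for the mean of 5 tissue lists, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each tumour. For components and similarity, 2000 genes were tried, and for the spread of subtype factors a prior count of 0.5. Chosen after seeing the data were another setting of edgeR's fit (legacy=FALSE), leaving out the tumours with the highest and the lowest tissue content, and, for the components, leaving out X- and Y-linked genes or sgControl replicate 6, and, for the Ddx3y reads and the exact tests of Neurod1 and of Kdm6a relative to other X-linked genes, counting tumours of 1 title number once. The list for tissue content overlaps the cell type lists it was applied to.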

Results

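Gene expression was measured by RNA sequencing in 13 mouse small cell lung cancer tumours. The tumours were of the RPP model, in which guide RNAs target Rb1, Trp53 and Rbl2 in mice that express Cas9 once a stop cassette is removed. A further guide was a control guide (sgControl, n = 6) or a guide against Kdm6a (sgKdm6a, n = 7), the gene of the histone H3 demethylase KDM6A, also called UTX. The deposited table held between 16835726 and 22910187 gene counts per tumour. At these totals 3 counts corresponded to between 0.131 and 0.178 CPM (counts scaled to the library size) of the total count, a limit that covers counting error only. All other CPM values are on library sizes scaled by TMM. The labels do not say which tumours came from one animal. In the sgKdm6a titles 3 numbers are each shared by a pair of tumours, told apart by L and R or by a running number. Such a pair may be of one animal. The main p-values take every tumour as a separate replicate, so they measure the spread between tumours that may not all be independent.

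The guide targets were examined first. Kdm6a mRNA (ENSMUSG00000037369, chromosome X, 18162575 to 18279936 in mm10) was present in every tumour, at 51.7 to 112 CPM in sgControl and 42.7 to 91.3 CPM in sgKdm6a tumours. Its mean was 6.06 ± 0.44 log2 CPM (SD, n = 6) in sgControl and 5.94 ± 0.36 log2 CPM (SD, n = 7) in sgKdm6a tumours. The Kdm6a log2 fold change was -0.14 (SE 0.22, edgeR adjusted p = 0.887), and it was 0.051 without sgControl replicate 4. Trp53, which encodes the tumour suppressor p53, had a log2 fold change of -1.06 (SE 0.30), with 3 of the 7 sgKdm6a tumours below every sgControl tumour. The edgeR p for Trp53 was 0.00326 unadjusted, 0.419 adjusted over all genes and 0.0131 adjusted over the list alone, that list being the 4 guide targets. These p take sgKdm6a tumours with a shared title number as independent, which the labels do not show. Rb1 and Rbl2, both of the retinoblastoma family, had log2 fold changes of 0.22 (SE 0.23) and -0.42 (SE 0.30), with edgeR adjusted p of 0.799 and 0.685. Cas9 cuts leave small insertions and deletions that need not lower an mRNA, so gene counts alone do not check which alleles were disrupted. With a term for tissue content, the Trp53 log2 fold change was -0.55 (SE 0.30).

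Sex-linked reads were unevenly spread over the groups. Ddx3y, a helicase gene on the Y chromosome, had 952 to 1609 counts in sgControl replicates 1, 2, 3, 5 and 6 and 2124 counts in sgKdm6a replicate 3. It had 0 counts in sgControl replicate 4 and in the other 6 sgKdm6a tumours, which allows up to 3 counts in each. Xist, the RNA that silences an X chromosome in female cells, was at 407 CPM in sgControl replicate 4 and at 899 CPM or above in those 6 sgKdm6a tumours, and at 2.66 CPM or below in the tumours with Ddx3y reads. Reads of Ddx3y were thus present in 5 of 6 sgControl and 1 of 7 sgKdm6a tumours at a minimum of 100 counts, which was chosen after the values were seen (Fisher's exact test, two-sided p = 0.0291). Counted by title number, which was also chosen after the values were seen, they were present in 5 of 6 and 1 of 4 numbers (Fisher's exact test, two-sided p = 0.190). Of 538 X-linked genes tested, 86 (16%) had a higher level in sgKdm6a tumours at an unadjusted edgeR p under 0.05, against 441 (2.75%) of the other genes. With a term for the Y-linked genes these were 36 (6.69%) and 642 (4.0%), and the Kdm6a log2 fold change was -0.59 (SE 0.22, edgeR unadjusted p = 0.019, adjusted p = 0.718).

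**Figure D1:**
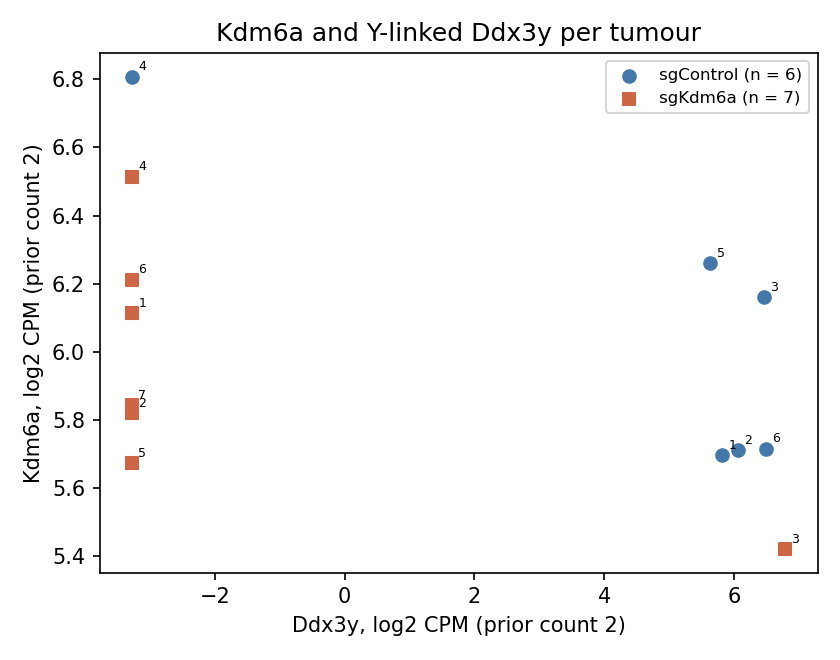
Kdm6a against the Y-linked gene Ddx3y, both as log2 CPM with a prior count of 2; each point is a tumour, numbered by replicate, with circles for sgControl (n = 6) and squares for sgKdm6a (n = 7). Ddx3y reads were found in 5 sgControl tumours and 1 sgKdm6a tumour, and the highest Kdm6a value, 6.81, belonged to sgControl replicate 4, which had none.

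The series asks whether Kdm6a regulates the subtype of small cell lung cancer, which is read from transcription factors that include NEUROD1, POU2F3 and YAP1. Neurod1 mRNA (ENSMUSG00000034701, chromosome 2, 79452521 to 79456751), which encodes a neurogenic factor, was at 0 to 3.46 CPM in sgControl and 1.14 to 106 CPM in sgKdm6a tumours. Its level was above every sgControl tumour in 6 of 7 sgKdm6a tumours, the exception being replicate 6 with 23 counts. The 2 highest Neurod1 levels, 106 and 62.2 CPM, were in sgKdm6a replicates 1 and 3.

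The Neurod1 log2 fold change was 5.09 (SE 1.19, edgeR unadjusted p = 8.17e-04), and the mean was -0.81 ± 2.13 log2 CPM (SD, n = 6) in sgControl and 4.43 ± 2.03 log2 CPM (SD, n = 7) in sgKdm6a tumours (exact permutation test, two-sided p = 0.00233). With the mean taken over tumours of 1 title number, the exact permutation p was 0.00952. The edgeR adjusted p was 0.419 over all genes and 0.00245 adjusted over the list alone, the list being the subtype factors that were tested. DESeq2 and edgeR both took tumours with a shared title number as independent, and DESeq2 gave Neurod1 an adjusted p of 6.63e-04. The title numbers form a lower series (3 sgControl, 2 sgKdm6a tumours) and a higher series (3 sgControl, 5 sgKdm6a). Both sgKdm6a tumours of the lower series share a title number and may come from the same animal. Within the lower series the Neurod1 log2 fold change was 6.40 (SE 1.52), and within the higher series it was 4.20 (SE 1.57). Yap1, a transcriptional co-activator of the Hippo pathway, was below every sgControl tumour in 4 of 7 sgKdm6a tumours and had a log2 fold change of -1.80 (SE 0.61, edgeR adjusted p = 0.419 over all genes and 0.0161 adjusted over the list alone). The edgeR p for Yap1 takes tumours with a shared title number as independent. Without sgControl replicate 6, at 90.0 CPM of Yap1 against 6.73 to 13.2 CPM in the other sgControl tumours, the Yap1 log2 fold change was -0.53 (SE 0.29). It was 0.014 (SE 0.47) in the lower series, -2.78 (SE 0.74) in the higher series and 0.0070 (SE 0.35) with a term for tissue content. The higher series holds sgControl replicate 6 and the lower does not, so the series contrast is not separate from that tumour. Pou2f3, the tuft cell factor, had 0 to 7 counts per tumour and was not tested. The MYC family genes Myc, Mycl and Mycn had log2 fold changes of 0.20 (SE 0.63), 0.19 (SE 0.69) and -0.64 (SE 1.26), with edgeR adjusted p of 0.953, 0.960 and 0.912. The Mycn value rests on single tumours: it was -3.11 (SE 1.04) without sgKdm6a replicate 3 and 1.19 (SE 1.21) without sgControl replicate 1.

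**Figure D2:**
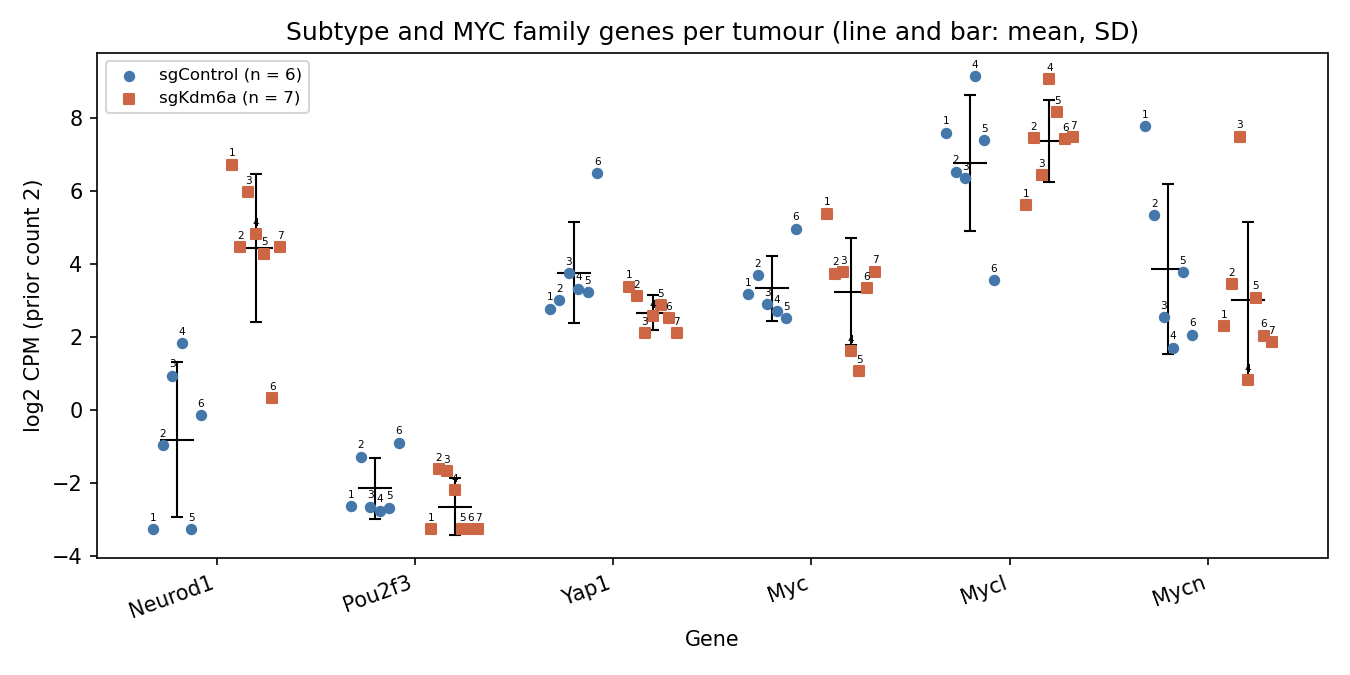
Log2 CPM (prior count 2) of 3 subtype genes and 3 MYC family genes in each tumour, numbered by replicate, with circles for sgControl (n = 6) and squares for sgKdm6a (n = 7); horizontal lines are means and bars are SD. Neurod1 in sgKdm6a tumours ranged from 0.32 in replicate 6 to 6.72 in replicate 1.

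A second question about subtype was whether the factors varied more between tumours of one genotype. The mean absolute deviation of Neurod1 from the group median was 1.69 log2 CPM in sgControl and 1.21 log2 CPM in sgKdm6a tumours (exact permutation test, two-sided p = 0.557). The deviations were, for Yap1, 0.76 and 0.38 (exact p = 0.725) and for Pou2f3 0.55 and 0.61 (exact p = 0.842). These 3 differences did not pass, each with an adjusted exact p of 0.842. The groups were not centred before permutation, so a shift in mean level widens the permuted deviations. For Neurod1 and Yap1, whose mean levels differed, these p therefore do not decide whether the spread differed. Neurod1 was near the detection limit in sgControl tumours, so its deviation there depends on the prior count: it was 2.36 log2 CPM with a prior count of 0.5, and on log2(FPKM + 1) the deviations were 0.33 and 0.95, the opposite order. The order also turned for Yap1 without sgControl replicate 6 (0.26 and 0.38) and for Pou2f3 on log2(FPKM + 1) (0.045 and 0.033). Pou2f3, at 0 to 7 counts, was near the limit of 3 counts, and with a prior count of 0.5 its deviations were 0.81 and 1.26.

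The genes of smallest p over the whole transcriptome were then listed. Pax6, a neural and endocrine transcription factor, was above every sgControl tumour in all 7 sgKdm6a tumours, with a log2 fold change of 4.03 (SE 0.83). Fam90a1b (2.91, SE 0.56), Tmsb15b1 (1.61, SE 0.30) and Rbm3 (1.08, SE 0.23), 3 X-linked genes, were also above every sgControl tumour in all 7. At an unadjusted edgeR p under 0.05, 16% of X-linked genes were higher, against 2.75% of the others, and Ddx3y reads were unevenly spread. Sex and genotype are therefore not separated for these 3 genes. Ttn, the gene of titin, had a log2 fold change of 2.97 (SE 0.66). In the other direction, Slc26a9, an epithelial chloride transporter gene, had a log2 fold change of -3.90 (SE 0.79) and lay below every sgControl tumour in all 7 sgKdm6a tumours, as did AW046200 (-1.86, SE 0.37). Il33, the gene of an epithelial alarmin cytokine, had a log2 fold change of -4.02 (SE 0.83), Enpep, an aminopeptidase gene, -3.60 (SE 0.66) and Fam78a -2.42 (SE 0.48). These 10 genes had the smallest p in each direction and did not pass, each with an edgeR adjusted p of 0.419.

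Of 16575 genes tested with edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.419. At an unadjusted p under 0.05 there were 1683 genes (10.2%), 527 higher and 1156 lower in sgKdm6a tumours. DESeq2 called 65 genes, 26 higher and 39 lower, among them Neurod1 and all 10 genes of smallest p. It was run with its defaults and gave no adjusted p to 742 genes. Those defaults handle outlying counts differently in the smaller sgControl and the larger sgKdm6a group, and the effect of this on the calls was not tested. The groups did not overlap for 47 genes (0.284%), where chance gives 0.117% if all 13 tumours are independent. The labels do not show that independence, and X-linked genes also enter the count while sex-linked reads were unevenly spread. An excess over chance is therefore not established. Without sgControl replicate 6 the number at an unadjusted p under 0.05 was 932, with 463 higher and 469 lower.

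Lists of genes fixed before the data were examined were then compared, and camera called 15 of 34, with 12 lower and 3 higher in sgKdm6a tumours. These calls rest on camera's preset correlation: 0 lists passed with an estimated correlation (smallest adjusted p = 0.529) and 0 by fry (smallest adjusted p = 0.417). Markers of alveolar type 2 cells, which make surfactant, had a median log2 fold change of -3.43, with 8 of 10 members lower at an unadjusted p under 0.05 and 8 adjusted over the list alone; Sftpd had -4.44 (SE 1.20) and Lamp3 -4.21 (SE 1.17). Alveolar type 1 markers had a median of -2.32 with 6 of 10 members lower and 5 adjusted over the list alone (Aqp5 -2.83, SE 0.66, and Ager -3.74, SE 0.99). Endothelial markers had a median of -2.10 with 9 of 13 members lower and 9 adjusted over the list alone, such as Cdh5 (-2.87, SE 0.72) and Tie1 (-2.80, SE 0.74). Macrophage markers had a median of -2.02 with 11 of 16 members lower and 9 adjusted over the list alone, such as Lyz2 (-3.60, SE 0.96) and Itgam (-4.30, SE 1.22). In no list did a member pass the edgeR adjustment over all genes.

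Camera placed these 4 lists below other genes, with adjusted p of 5.63e-08 for alveolar type 2 and for endothelial markers, 1.77e-05 for alveolar type 1 and 0.00409 for macrophage markers. Fibroblast and pericyte markers (7 of 14 members lower, 0 adjusted over the list alone; Postn -1.88, SE 0.56, Col1a1 -2.38, SE 0.87) had a camera adjusted p of 0.00559. T and NK cell markers (0 of 7 at an unadjusted p under 0.05; Il7r -1.23, SE 0.63, Trac -1.51, SE 0.79) had 0.00688. With an estimated correlation between genes, none of the 34 lists tested passed, with an adjusted p = 0.529 for the endothelial, alveolar and T and NK cell lists, 0.592 for macrophages and 0.579 for fibroblasts. The sgControl tumour of replicate 6 stood apart in these lists: its mean over 5 of them was 6.79 log2 CPM, against 3.30 to 3.81 in the other sgControl and 1.79 to 4.0 in the sgKdm6a tumours. Without it camera kept the endothelial, alveolar type 2 and alveolar type 1 lists (adjusted p of 5.45e-08, 2.52e-06 and 7.22e-04). Their medians were then -0.70, -1.80 and -0.49, with 4, 0 and 1 members lower adjusted over the list alone. The macrophage list, with 0 such members, had a camera adjusted p of 0.855 without that tumour, the fibroblast list 0.370 and the T and NK cell list 0.0521; their medians were then -0.034, -0.097 and -0.47. The T and NK cell list also lost its call without sgKdm6a replicate 3 (adjusted p = 0.0608), and without sgKdm6a replicate 1 only 4 of its members passed the filter, so that it was not tested.

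**Figure D3:**
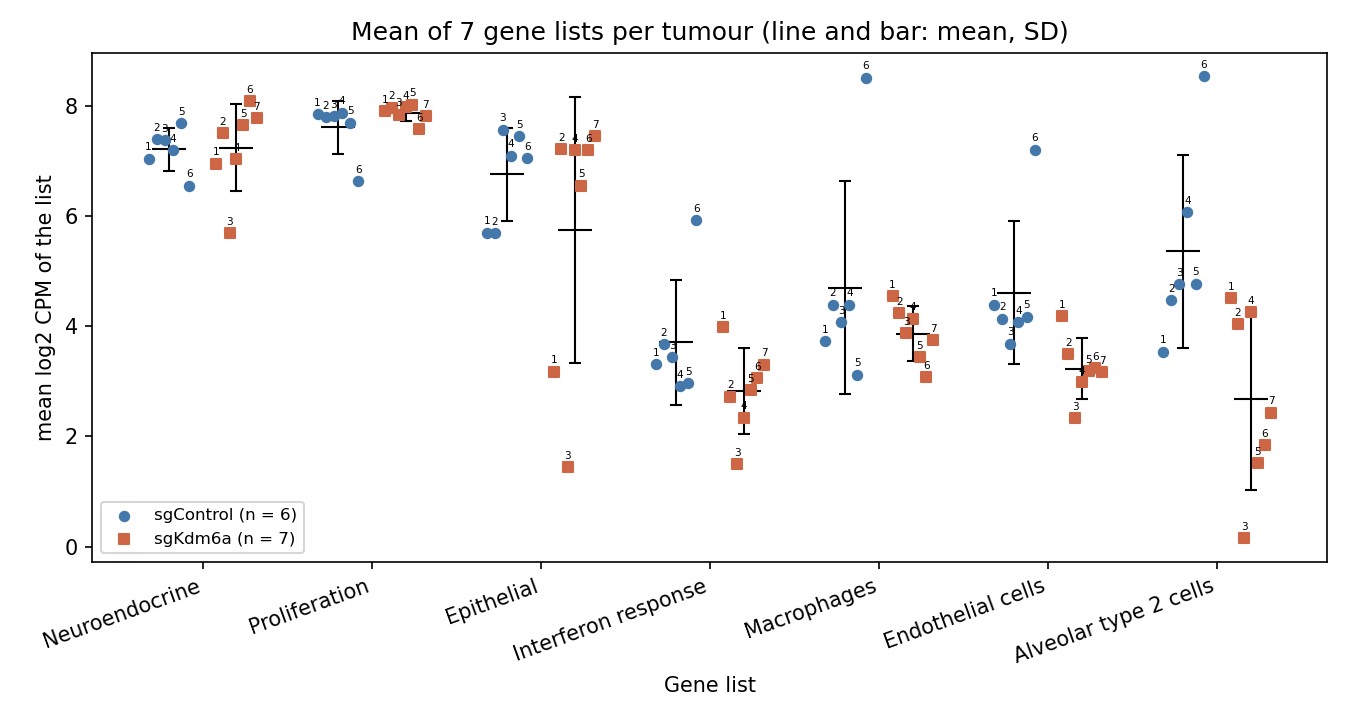
Mean log2 CPM of 7 gene lists in each tumour, numbered by replicate, with circles for sgControl (n = 6) and squares for sgKdm6a (n = 7); horizontal lines are means and bars are SD. The macrophage mean was 8.51 in sgControl replicate 6, and the epithelial mean was 3.18 and 1.44 in sgKdm6a replicates 1 and 3.

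Immune and non-neuroendocrine programmes had the same direction. Interferon response genes had a median log2 fold change of -1.37, with 12 of 26 members lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (Gbp2 -2.84, SE 0.98, Mx1 -2.57, SE 0.89; camera adjusted p = 1.12e-06). Non-neuroendocrine and YAP1-associated genes had a median of -1.65, with 11 of 19 members lower and 6 adjusted over the list alone (Anxa3 -2.89, SE 0.79, Ajuba -2.71, SE 0.83; camera adjusted p = 1.07e-05). Genes of antigen presentation by MHC class I (Psmb10 -1.19, SE 0.48, B2m -1.31, SE 0.58) had 2 of 13 members lower, and those of MHC class II (H2-DMa -1.55, SE 0.63, Cd74 -1.55, SE 0.65) 4 of 8, with 0 adjusted over the list alone in either and camera adjusted p of 0.00105 and 0.00129. With an estimated correlation, the adjusted p was 0.529 for the interferon, YAP1-associated and class II lists and 0.550 for class I. Without sgControl replicate 6, the interferon median was -0.35 and the YAP1-associated median -0.35, with camera adjusted p of 0.00346 and 0.0036 and 0 members of either lower adjusted over the list alone. The class I and class II medians were then -0.043 and -0.13 (camera adjusted p of 0.0479 and 0.0482), and class I lost its call without sgKdm6a replicate 3 (0.0608). With a term for tissue content none of these 4 lists passed, and their direction turned.

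Lists of subtype identity followed. Of 22 neuroendocrine genes, 2 were higher at an unadjusted p under 0.05 and 0 adjusted over the list alone: Uchl1 (0.55, SE 0.22) and Syp (0.66, SE 0.27), with a camera adjusted p of 0.362. In the NEUROD1-associated list, which holds Neurod1 itself, 1 of 8 members was higher, and it alone passed adjusted over the list alone; Hes6 had a log2 fold change of 0.59 (SE 0.36), and the camera adjusted p was 0.0257, or an adjusted p of 0.529 with an estimated correlation. Camera gave the NEUROD1-associated list an adjusted p of 0.146 without sgControl replicate 6, 0.0526 without sgKdm6a replicate 2 and 0.0598 without sgKdm6a replicate 5. The call also ended with the tissue term (0.928) and with the Y-linked term (0.139). Without sgKdm6a replicate 3 the neuroendocrine list had 0.0144. Of 11 tuft cell genes 1 was lower, Ptgs1 (-1.81, SE 0.76), with Ltc4s at -1.09 (SE 0.61) and a camera adjusted p of 0.232. Without sgControl replicate 6 none of the tuft cell genes was lower, the median of that list went from -0.83 to 0.12, and Ltc4s was at 0.12. Ptgs1 was also at 0.63 with the tissue term and 0.66 in the lower series, which does not hold that tumour.

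Proliferation and synaptic genes lay above other genes by camera. The proliferation list had a median log2 fold change of 0.26 with 1 of 23 members higher at an unadjusted p under 0.05 (Cdk1 0.44, SE 0.19; Tyms 0.33, SE 0.18) and an adjusted p of 9.15e-05. The synaptic list had a median of 0.36 with 2 of 21 members higher (among them Syp, 0.66, SE 0.27) and an adjusted p of 0.00559. With an estimated correlation both had an adjusted p of 0.529, and without sgControl replicate 6 camera gave adjusted p of 0.162 and 0.299. The Y-linked term ended both calls (0.141 and 0.794), and with the tissue term both lists turned to lower (0.728 and 0.928). Hox genes, which set position along the body axis, had a median of -0.48 with 1 of 9 members lower (Hoxa5 -1.77, SE 0.80; Hoxb9 -2.15, SE 1.43), and epithelial junction genes a median of -0.15 with 0 of 16 members lower (Esrp2 -1.03, SE 0.71; Cldn4 -0.76, SE 0.82). Their camera adjusted p were 0.00718 and 0.00559, or adjusted p of 0.529 and 0.592 with an estimated correlation, and without sgKdm6a replicate 1 the camera values were 0.138 for Hox and 0.133 for epithelial genes. Without sgKdm6a replicate 3 the epithelial value was 0.338.

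Camera called none of the remaining 19 lists. Among lists tied to chromatin, 0 of 11 genes of the KDM6A and COMPASS complex list and 0 of 11 of Polycomb repressive complex 2 reached an unadjusted p under 0.05 (camera adjusted p of 0.661 and 0.480). The Notch pathway had 3 of 17 members lower (0.12), the MYC network 0 of 10 (0.313), mesenchymal genes 5 of 11 lower (0.12), axon guidance genes 2 higher and 1 lower of 25 (0.661), photoreceptor genes 2 higher and 1 lower of 6 (0.458), surface antigens 2 of 10 lower (0.124) and hypoxia genes 0 of 15 (0.234). Adjusted over the list alone, 4 mesenchymal genes, 1 surface antigen gene and 1 neutrophil gene were lower. Among markers of other cells, B and plasma cells had 2 of 10 lower (0.0596), neutrophils 4 of 6 lower (0.232), club cells 1 higher and 1 lower of 9 (0.458), ciliated cells 2 of 10 higher (0.210), erythroid cells 0 of 5 (0.12), muscle 1 higher and 1 lower of 8 (0.602) and mesothelium 0 of 5 (0.576). Hepatocyte, adipocyte and Y-linked lists had 3, 1 and 4 tested members, under the minimum of 5, with 1, 1 and 0 of them lower at an unadjusted p under 0.05 and as many adjusted over the list alone. The median and the mean differed in sign for the KDM6A and COMPASS list (0.091 and -0.11), photoreceptor genes (0.40 and -0.0056) and hepatocyte markers (0.025 and -0.91), and camera's direction differed from the median for axon guidance genes (-0.15) and erythroid markers (0.39). Without sgControl replicate 6, 1 mesenchymal gene was lower and 0 adjusted over the list alone, and that median went from -1.30 to 0.18. Of the neutrophil genes 1 was then lower, with a median that went from -3.07 to 0.84, and 1 Notch, 1 surface antigen (0 adjusted over the list alone) and 0 B and plasma cell genes were lower. Medians also turned for axon guidance genes (0.31), mesothelium (-0.68 to 0.74) and the KDM6A and COMPASS list (0.091 to -0.0017). Leaving out a single tumour brought some of these lists under 0.05. B and plasma cells passed without sgControl replicate 2, 3 or 5 or sgKdm6a replicate 1, 2 or 4 (lowest 0.00294), mesenchymal genes without sgControl replicate 3 or 5 or sgKdm6a replicate 1 (lowest 0.0294), hypoxia genes without sgControl replicate 2 or sgKdm6a replicate 6 (lowest 0.0216), ciliated cells without sgControl replicate 3 (0.0229), neutrophils without sgControl replicate 5 (0.0447) and erythroid cells without sgControl replicate 5 or sgKdm6a replicate 3 (lowest 3.18e-05).

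The tumours were also compared over the 500 most variable genes. The first principal component held 35.7% of the variance and placed sgKdm6a replicate 3 at -79.8 and replicate 1 at -41.4, with the other sgKdm6a tumours between -0.187 and 17.7. Its mean score was 12.5 in sgControl and -10.7 in sgKdm6a tumours (exact permutation test, two-sided p = 0.249). The second held 17% and had a mean of 14.7 in sgControl and -12.6 in sgKdm6a tumours (exact permutation p = 0.0321). Its largest loadings were of sex-linked genes, with Xist (-0.208) at the sgKdm6a end and Ddx3y (0.177), Eif2s3y (0.166), Uty (0.149) and Kdm5d (0.148) at the other. With X- and Y-linked genes left out, the exact p for the second component was 0.0897. On log2(FPKM + 1) it was 0.0746, and with counts summed over shared title numbers 0.171. The highest second score, 50.4, belonged to sgControl replicate 6, which also had the highest mean over the tissue lists, and without that tumour the exact p was 0.024.

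**Figure D4:**
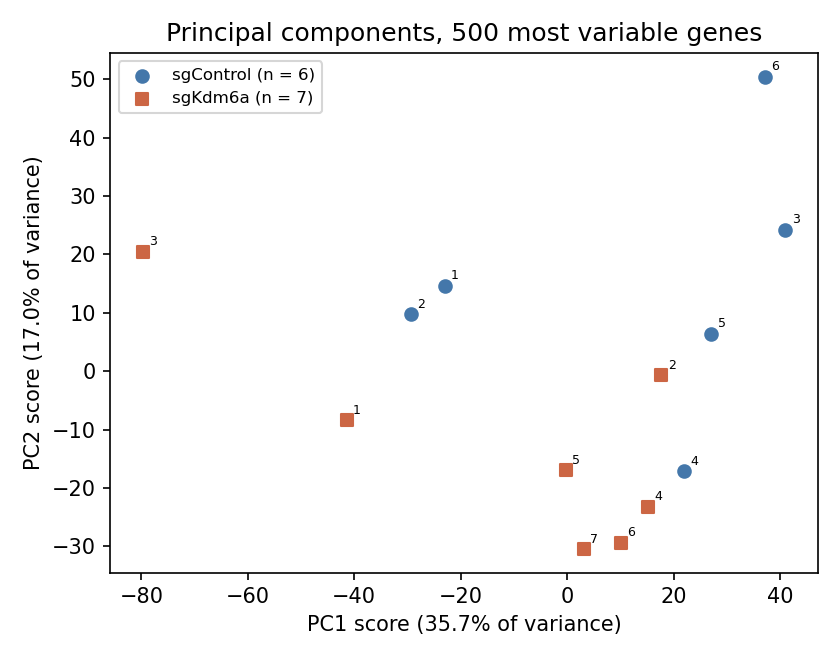
Scores of each tumour on the first 2 principal components of the 500 most variable genes, in log2 CPM, numbered by replicate, with circles for sgControl (n = 6) and squares for sgKdm6a (n = 7). The first component separates sgKdm6a replicate 3, at -79.8, from the other tumours, and sgControl replicate 6 has the highest second score, 50.4.

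Tumours sharing a title number were compared with other pairs of sgKdm6a tumours. The mean Pearson correlation across genes, which are not independent replicates, of deviations from the group mean was -0.043 over the 3 pairs with a shared number and -0.17 over the others. In order of their number, the 3 pairs had -0.31, -0.05 and 0.23. Deviations from the mean of these same tumours are negatively correlated on average, so a negative value alone does not mean that tumours are unlike. Of 105 ways to pair 6 of the 7 tumours, a share of 0.190 gave a mean as high (exact permutation test, one-sided p = 0.190) and this test did not detect a higher similarity of tumours with a shared number. Fitted to all genes with genotype in the model, the consensus correlation of tumours sharing a number was 0.254, which this test does not assess.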

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

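Chosen after the result was seen were the tests over title numbers, the test of Neurod1 with a term for the Y-linked genes and the test of the T and NK cell, macrophage and fibroblast lists without sgControl replicate 6. Within each genotype, the highest or lowest tumour was compared with the others by its gap over the group's range (Dixon's 95% critical value), for 98 groups of values. A tumour stood apart in 23 of them, where chance gives about 1 in 20, and 17 of the 23 belonged to sgControl replicate 6. Lists share tumours and some genes, so these are not independent.

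In sgControl replicate 6 the mean log2 CPM was high for macrophage (8.51), MHC class I (8.07), mesenchymal (7.73), alveolar type 1 (7.68), fibroblast (7.27), non-neuroendocrine and YAP1 (7.26), endothelial (7.21), MHC class II (6.32), neutrophil (6.16), interferon (5.93), mesothelial (3.99) and T and NK cell (2.44) lists, and for Yap1 itself (6.49). In the same tumour it was low for proliferation (6.63), Polycomb repressive complex 2 (6.23), synaptic (4.49) and NEUROD1-associated (3.31) lists. The sgKdm6a tumour of replicate 3 stood apart with Mycn at 7.49 log2 CPM, erythroid genes at 6.98, the KDM6A and COMPASS list at 6.56 and hepatocyte genes at -1.27. The KDM6A and COMPASS list holds the Y-linked gene Uty, and replicate 3 was the only sgKdm6a tumour with Ddx3y reads. Its mean over the Y-linked list was 6.33 log2 CPM, against -2.62 or below in the other sgKdm6a tumours. The sgKdm6a tumour of replicate 6 stood apart with low Neurod1, at 0.32 log2 CPM, and a low NEUROD1-associated list, at 4.70.

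The first pattern weighed is the higher Neurod1 mRNA in sgKdm6a tumours, a log2 fold change of 5.09 (SE 1.19). With a term for the Y-linked genes it was 4.96, and with a term for tissue content 5.37, each within 1 SE of that value. A lower share of normal tissue thus does not account for it as far as that term measures it. Only 1 sgKdm6a tumour had Ddx3y reads and only 1 sgControl tumour had none. The Y-linked term therefore largely follows genotype, and it does not decide whether sex contributes. Chance stays open beyond the exact permutation p of 0.00233, since Neurod1 did not pass the adjustment of edgeR over all genes. An effect of the Kdm6a guide is a candidate explanation that the design names and that these tumours alone do not separate from an unrecorded difference between animals.

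The second pattern is the lower level of normal lung, immune and stromal markers in sgKdm6a tumours, where camera called 6 cell type lists lower. Without sgControl replicate 6, 3 of the 6 lists kept their call (endothelial, alveolar type 2 and alveolar type 1), while 0 of the other 3 lists (T and NK cells, macrophages, fibroblasts and pericytes) kept it. The calls of those 3 do not rest on that tumour alone, but their medians shrank to -0.70, -1.80 and -0.49, and a kept call is weak evidence because the other splits below gave a median of 11 lists. With a term for the Y-linked genes 4 of the 6 kept their call. That term largely follows genotype and a kept call is weak evidence, so this does not decide whether sex is the cause. None of the 6 passed camera with an estimated correlation (smallest adjusted p = 0.529). How much normal tissue was taken with each tumour may differ between the groups for reasons other than genotype, and this was not tested.

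The third pattern is Kdm6a mRNA that was not detectably lower in sgKdm6a tumours. Kdm6a escapes X inactivation, and Xist and Ddx3y reads were unevenly spread over the groups, so sex could hide a fall. Relative to the mean of Ddx3x, Eif2s3x and Kdm5c, which share that property, Kdm6a was -1.45 ± 0.19 log2 CPM (SD, n = 6) in sgControl and -2.03 ± 0.33 log2 CPM (SD, n = 7) in sgKdm6a tumours. The difference of -0.58 (exact permutation test, two-sided p = 0.00816, and 0.00476 with the mean taken over tumours of 1 title number) is what this explanation needs. The 3 reference genes did not move alike: log2 fold changes were 0.82 for Eif2s3x, 0.38 for Ddx3x and 0.20 for Kdm5c. With a term for the Y-linked genes they were 0.40, 0.27 and -0.22. In sgKdm6a replicates 4 and 6 the relative Kdm6a level (-1.52 and -1.60) lay within the sgControl range of -1.63 to -1.21. With a term for tissue content the Kdm6a log2 fold change was -0.16 against -0.14 without it. That term has the same slope in both genotypes, whereas reads from tissue without the guide would matter in sgKdm6a tumours alone. It also measures only the cell types in its lists, so it does not decide on that explanation.

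The counts were set against 100 splits of the 13 tumours into 6 and 7, the real one included. For genes at an unadjusted p under 0.05, 16 of 100 splits gave at least the real 1683, and the highest other gave 3287. For genes past the edgeR adjusted p the real count was 0, so that 100 of 100 splits had to give as many, and this comparison says nothing about chance. The highest other split gave 184 such genes, which points to a structure of the samples whose source was not tested. For lists past camera, 23 of 100 splits gave at least the real 15, with 20 in the highest other. Chance is not excluded for the number of genes at an unadjusted p under 0.05 or for the number of lists.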

How the results depend on the processing

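Chosen after the data were seen were legacy=FALSE in the edgeR fit, leaving out both sgControl replicate 6 and sgKdm6a replicate 3, and, for the components, leaving out X- and Y-linked genes or sgControl replicate 6. Counting tumours of 1 title number once was too: Fisher's exact p for Ddx3y reads rose from 0.0291 to 0.190. No paired analysis was possible because no label pairs an sgControl with an sgKdm6a tumour. DESeq2, with its default handling of outlying counts, called 65 genes, and every other alternative called 0, as edgeR did. Of the 65, 64 had an unadjusted edgeR p under 0.05; the other, Col7a1, had log2 fold changes of -2.23 in DESeq2 and 0.39 in edgeR. Of the 50 tested genes that the naming rule takes and that are reported here, 31 kept their direction under every alternative, and 14 passed an adjusted p, all in DESeq2. Cerkl and Col7a1, named after their values were seen, are not among the 50 and also passed in DESeq2 (adjusted p of 0.00529 and 0.0222). The genes at an unadjusted p under 0.05 numbered 3262 with no low-count filter, 946 with counts summed over shared title numbers, 875 with duplicateCorrelation, 894 in the lower number series, 1093 with the Y-linked term and 1059 on log2(FPKM + 1). Camera's 15 lists became 0 with an estimated correlation, 0 by fry, 2 with the tissue term, 6 with both tumours left out and 9 to 19 with a tumour left out. The tissue term holds 5 of the lists it was applied to, so it cannot test those. For the second component the exact p was 0.0746 on log2(FPKM + 1), 0.0897 without X- and Y-linked genes and 0.171 with summed counts, which leave fewer samples. In simulations of this design 14.8% of genes changed by 1 on the log2 scale were recovered, which limits what depth and spread can show. Those simulations held no outlying or related tumours.

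The cause of the following reversals was not tested. Mycn was 0.024 with summed counts, 0.90 summed also over the prefix, 0.69 with a series term, 2.52 in the higher series and 0.85 with the Y-linked term. It moved the other way, from -0.64, to -2.94 in DESeq2 (adjusted p = 0.0727), -3.13 with the tissue term, -3.49 in the lower series, -3.35 with both tumours left out and -1.58 with quality weights. Mycl was -0.18 summed also over the prefix, -0.045 with a series term, -0.13 in the lower series, -0.70 with the Y-linked term and -0.69 with the tissue term. Myc was -0.0095 with duplicateCorrelation, -0.79 in the higher series and -0.079 on log2(FPKM + 0.1). Ltc4s was 0.26 with quality weights, 0.25 in the lower series, 0.73 with the tissue term and 0.19 with both tumours left out. In the lower series Kdm6a was 0.097, Yap1 0.014, Hes6 -0.059, Ptgs1 0.66, Ajuba 0.11, Hoxa5 1.11, Gbp2 0.43, Trac 0.17 and Col1a1 0.23. That series does not hold sgControl replicate 6. Hoxb9 was 0.88 in the higher series. With the tissue term Rb1 was -0.027, Yap1 0.0070, Ptgs1 0.63, Hoxa5 0.40, H2-DMa 0.41, Cd74 0.14, Gbp2 0.37, Il7r 0.018, Itgam 0.69 and Col1a1 0.22.

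Lists that turned with the tissue term had camera adjusted p of 0.364 (YAP1-associated and MHC class II), 0.728 (proliferation), 0.981 (MHC class I), 0.403 (interferon), 0.928 (synaptic, T and NK cells), 5.46e-04 (macrophages) and 0.164 (fibroblasts), and erythroid markers turned with the Y-linked term (0.042). That term ended the call of the NEUROD1-associated (0.139), Hox (0.0849), proliferation (0.141), synaptic (0.794), macrophage (0.141) and fibroblast (0.529) lists, and brought muscle (0.00813, higher) and B and plasma cells (0.0129, lower) under 0.05. Ciliated cells passed with summed counts (0.0363, higher) and erythroid cells with both tumours left out (3.87e-04, lower). The difference in spread was 0.62 for Neurod1 and -0.012 for Pou2f3 on log2(FPKM + 1), and -0.05 for Pou2f3 with summed counts. With a tumour left out, log2 fold changes ranged from -0.25 to 0.051 for Kdm6a, -0.39 to 0.75 for Myc, -0.24 to 0.95 for Mycl, -3.11 to 1.19 for Mycn and -1.30 to 0.12 for Ltc4s, and differences in spread from -0.10 to 0.31 for Pou2f3 and -0.51 to 0.12 for Yap1.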

Other observations

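The test of the region around Neurod1 was written before the neighbours' values were seen, and Cerkl was chosen after its own value was seen. The sgKdm6a tumours of replicates 1 and 3 had the lowest epithelial means, 3.18 and 1.44 log2 CPM, against 5.69 to 7.57 in sgControl and 6.55 to 7.45 in the other sgKdm6a tumours. The interaction of genotype with the number series of the titles had 0 genes past the edgeR adjusted p (smallest 0.712), with 1146 at an unadjusted p under 0.05, and no other tool was run for it.

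Cerkl (chromosome 2, 79330543 to 79456785), a ceramide kinase-like gene whose span covers that of Neurod1 on the same strand, had a log2 fold change of 3.68 (SE 0.84). A hypothesis was that the whole region moves. Of 3 other tested genes within 500 kb, 0 had a positive log2 fold change at an unadjusted p under 0.05: Itga4 had 0.65 (SE 0.61), Ssfa2 0.035 (SE 0.45) and Pde1a 1.91 (SE 0.98). None of these values was as large as that of Cerkl. All 3 are positive with wide SE, so they do not decide whether the region moves to a smaller extent. Reads from Neurod1 may be counted for Cerkl, or the reverse, and the counts cannot separate them.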
